A study of Homo sapiens and Mus musculus with 68 samples.

How the data were processed

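Chromatin immunoprecipitation with sequencing was made for FOXA1, Flag-tagged FOXA1, NIPBL, RAD21, CTCF and H3K27ac in 68 samples, 41 of them immunoprecipitations and 27 inputs. The inputs were not analysed here. Per the submitters' processing notes, FastQC, fastp, Bowtie2, MACS2 and bedtools were used and the genome builds were hg19 for human and mm10 for mouse; versions and settings are not given in the sources used here. The deposited peak lists give, for each peak, a fold enrichment, the ratio of the immunoprecipitation signal at the summit to its background as MACS2 writes it. The deposited lists also give a -log10 q value per peak, where q is a p-value adjusted for multiple testing. The smallest -log10 q was 2.00 (q of 0.00998) in the NIPBL, RAD21 and CTCF lists of the degradation experiment and 1.30 (q of 0.0499) in the other lists. The deposited H3K27ac lists give positions alone. No list gives read counts, so the depth of every sample is unknown, and differences in depth between lists were not corrected.

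The human build was checked from the coordinates: the largest end on chromosome 1 was 249240513, beyond the last gene end (248937099) of the gene table at hand, which is for GRCh38. Gene positions and sequence of hg19 and mm10 were not used here, so regions are named by coordinates, gene lists and motifs fixed at the start were not run, and coordinates are those of hg19 and mm10.

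Touching peaks within a list would have been merged, which joined 0 peaks. A control region was counted as lost when no region of the treated list overlapped it by at least 1 bp, and a treated region as gained when no control region overlapped it. FOXA1 occupancy came from the Flag-FOXA1 wild-type list for 22Rv1 and from the LNCap control FOXA1 list for LNCap and A549. CTCF, RAD21 and H3K27ac occupancy came from the 22Rv1 lists at 0 h, also for LNCap and A549. The letters N and R in the labels were read as separate NIPBL and RAD21 knockdown experiments, each with its own control; this reading is an assumption, on which the knockdown losses and the comparison of the controls rest. Labels of the LNCap lists mention a blacklist, taken to mean that such regions were removed there; whether this was done for the other lists is unknown, which bears on very strong regions kept in several lines. WT and R219S NIPBL lists named as merged in the labels were taken as pooled over both replicates; replicate 2 enters through these alone.

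Each share carries an exact Clopper-Pearson 95% interval, and differences of shares carry Newcombe intervals. Both measure counting error within a list, not the spread between libraries. For a class of regions, 10000 random sets of control regions of the same size were drawn within 10 bins of fold enrichment, as a description and not a test; the loss of a class in LNCap and 22Rv1 was also compared with sets matched on -log10 q and on width. The level by chance was taken from 100 circular shifts of the regions along each chromosome. Strength groups split the control list into 4 equal parts by fold enrichment. Where replicates existed, means and SD over 2 lists are given. Tissue specificity in mouse was tested with a one-sided exact permutation test over 15 pairings of 6 libraries on the Jaccard index in base pairs, whose smallest possible p is 0.0667. Classes of fewer than 20 regions were not reported.

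The named regions follow a rule fixed in advance: per comparison, the 5 lost and the 5 kept control regions with the highest control fold enrichment, of which the strongest are printed. For mouse the same number of the strongest regions of each tissue alone is used; this extension was chosen after the data were seen, when the gene-based part of the rule could not be run. The main comparisons, the overlap rule, the main tests and the first set of alternatives were chosen before the data were examined. Several further splits were not among the comparisons fixed beforehand. These include NIPBL loss by H3K27ac, by the fate of FOXA1 in LNCap and by Flag-FOXA1 class in R219S. RAD21 loss by the fate of NIPBL, the overlap of RAD21 losses in both knockdowns, and matching on -log10 q and width were also not fixed beforehand. The alternatives were an overlap of at least 50% of the shorter region, peaks with -log10 q of at least 5, lists limited to the same number of strongest peaks, LNCap FOXA1 regions in 22Rv1, replicate-paired lists, and lists without a replicate. For H3K27ac, region width replaced strength. Restrictions to regions also found in a second control list, mouse FOXA1 sets of equal length in all tissues, R219S classes in replicate 1, and the search for the strongest regions and for regions at lost or kept NIPBL or H3K27ac in lists made without degradation were added after seeing the data, as were the class differences in such lists other than wild-type replicate 1.

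The calculations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The procedure was tested on simulated data: from the 26575 NIPBL regions at 0 h, losses of 9.69%, 30.1% and 60.0% were recovered as set, a class loss of 49.8% beside 19.4% elsewhere was recovered, and 96 of 100 losses that depended on strength alone fell inside the central 95% of the matched sets. The simulated losses depended on the same fold enrichment that was used for matching. They therefore do not test whether fold enrichment captures region strength in the real lists. The count of lost NIPBL regions after degradation, 9372, was also obtained with bedtools 2.31.1.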

Results

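The study addressed whether the pioneer factor FOXA1, a protein that binds closed chromatin, sets where the cohesin loader NIPBL and the cohesin subunit RAD21 are found on the genome. Binding was measured by ChIP-seq and is reported here from 41 lists of called regions, 29 from human cell lines and 12 from mouse tissue. The human lines were LNCap and 22Rv1, which are prostate carcinoma lines, and A549, a lung carcinoma line that the labels place under prostate cancer. FOXA1 was knocked down in LNCap and A549, and ETS1 was knocked down in A549. In 22Rv1 FOXA1 was degraded for 24 h with a dTAG system, was expressed with a Flag tag as wild type or as the mutant R219S, or was left in place while NIPBL or RAD21 was knocked down. Mouse liver, lung and stomach gave 2 libraries of FOXA1 and 2 of NIPBL each. Each human condition had 1 list, apart from H3K27ac with 2 replicates per time point and NIPBL in wild-type and R219S cells with a list of replicate 1 and a list pooled over both replicates. The human lists held 1349 to 100536 regions and the mouse lists 15783 to 82854. Read depth is unknown because the lists carry none. A control region was called lost when no treated region overlapped it by 1 bp or more, and a treated region was called gained when no control region overlapped it. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only; no human comparison other than H3K27ac has a separate list per replicate, so the spread between libraries is shown through control lists set against each other.

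Before any treatment NIPBL sat mostly at FOXA1 regions. In LNCap 92.7% of the 26343 NIPBL regions overlapped a FOXA1 region of the same line, against 3.20% after the regions were shifted around each chromosome. In 22Rv1 68.7% of the 26575 NIPBL regions at 0 h overlapped a Flag-FOXA1 region, 65.3% an H3K27ac region, 47.1% a RAD21 region and 39.5% a CTCF region; shifted regions gave 3.77%, 2.20%, 1.63% and 2.75%. RAD21 was placed differently, with 83.6% of its 41263 regions at CTCF and 37.0% at Flag-FOXA1. Of LNCap NIPBL regions 59.5% were present in 22Rv1 and 19.7% in A549, whose list was shorter, with 11343 regions. In the opposite direction 57.5% of 22Rv1 and 47.0% of A549 regions were present in LNCap. FOXA1 in 22Rv1 was read from the Flag-FOXA1 wild-type list, since FOXA1 lists of the degradation time points were not analysed here, so the degradation itself was not checked.

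After FOXA1 knockdown in LNCap most FOXA1 regions and most NIPBL regions were no longer called. FOXA1 fell from 86809 to 4495 regions, with 94.9% lost (interval 94.7 to 95.01) and 27 gained, and the genome it covered fell by 97.0%. NIPBL fell from 26343 to 3897 regions, with 86.6% lost (86.2 to 87.0) and 151 gained, and its covered genome fell by 90.0%. Weak regions were lost most: with NIPBL regions ranked by fold enrichment and split into 4 equal groups, 96.7% of the weakest group and 67.5% of the strongest were lost. For FOXA1 these shares were 99.9% and 81.4%. Treated lists this much shorter lower the shared part by themselves. When both lists were limited to the same number of strongest regions, 49.3% of FOXA1 and 50.2% of NIPBL regions were lost.

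In LNCap NIPBL was lost both at FOXA1 regions and away from them. NIPBL regions at FOXA1 were lost in 85.9% of cases and those away from FOXA1 in 95.2%, a difference of -9.34 points (-10.4 to -8.21). The difference shrank to -3.76 points with regions of -log10 q of at least 5 in the lists. Regions holding both FOXA1 and CTCF were kept best, with 79.2% lost, beside 89.5% at FOXA1 without CTCF and 95.03% at CTCF without FOXA1. Medians of sets matched on region width were nearly the same, at 79.3%, 89.4% and 94.6%. The order of these classes therefore cannot be told apart from an order by width. NIPBL regions marked by H3K27ac in 22Rv1 lost 80.5% and unmarked ones 96.1%. Where the FOXA1 region itself was kept, 87.9% of 2089 NIPBL regions were lost (86.5 to 89.3), more than the 85.7% of 22320 where FOXA1 was lost (85.3 to 86.2). The strongest lost FOXA1 regions lay on chromosome 6 (154911593 to 154912479, fold enrichment 74.8) and chromosome 1 (21664512 to 21665980, fold enrichment 70.1). The strongest kept ones lay on chromosome 11 (63932972 to 63934374, 76.5) and chromosome 4 (37009630 to 37010311, 75.1). Among NIPBL regions the strongest lost one lay on chromosome 8 (128030468 to 128031401, fold enrichment 31.1) and carried FOXA1, CTCF, H3K27ac and RAD21 signal. The strongest kept ones lay on chromosome 5 (37064583 to 37065024, 41.0) and chromosome X (52004540 to 52005214, 32.8).

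After either knockdown in A549 most NIPBL regions were no longer called, and the lost sets were more alike than independent draws. From 11343 control regions NIPBL fell to 2576 after FOXA1 knockdown, with 87.9% lost (87.3 to 88.5), and to 3110 after ETS1 knockdown, with 82.1% lost (81.4 to 82.8). The covered genome fell by 78.3% and by 78.9%. With lists of equal length the losses were 75.2% and 61.1%. Depth is unknown, so a loss of NIPBL cannot be told apart from shallower knockdown libraries. Of the control regions 8843 were lost under both knockdowns, where sets of equal size and equal strength drawn independently reached at most 8365; 902 were kept under both, against at most 424. The knockdowns share 1 control list, which by itself makes the lost sets alike. New regions were common: 46.4% of the FOXA1-knockdown regions and 31.3% of the ETS1-knockdown regions were absent from the control. Regions lost under both knockdowns overlapped LNCap NIPBL regions in 51.7% of cases and LNCap FOXA1 regions in 59.3%, while those kept under both did so in 24.0% and 44.5%. No FOXA1 or ETS1 list of A549 was used here. The strongest regions lost after FOXA1 knockdown, on chromosome 15 (102501524 to 102502260, fold enrichment 19.3) and chromosome 2 (33141226 to 33141695, 19.0), were lost under both knockdowns. The strongest region lost after ETS1 knockdown, on chromosome 17 (938408 to 939061, 23.6), was kept after FOXA1 knockdown. The strongest region of the control, on chromosome 1 (911843 to 913450, 35.3), was kept under both.

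**Figure D1:**
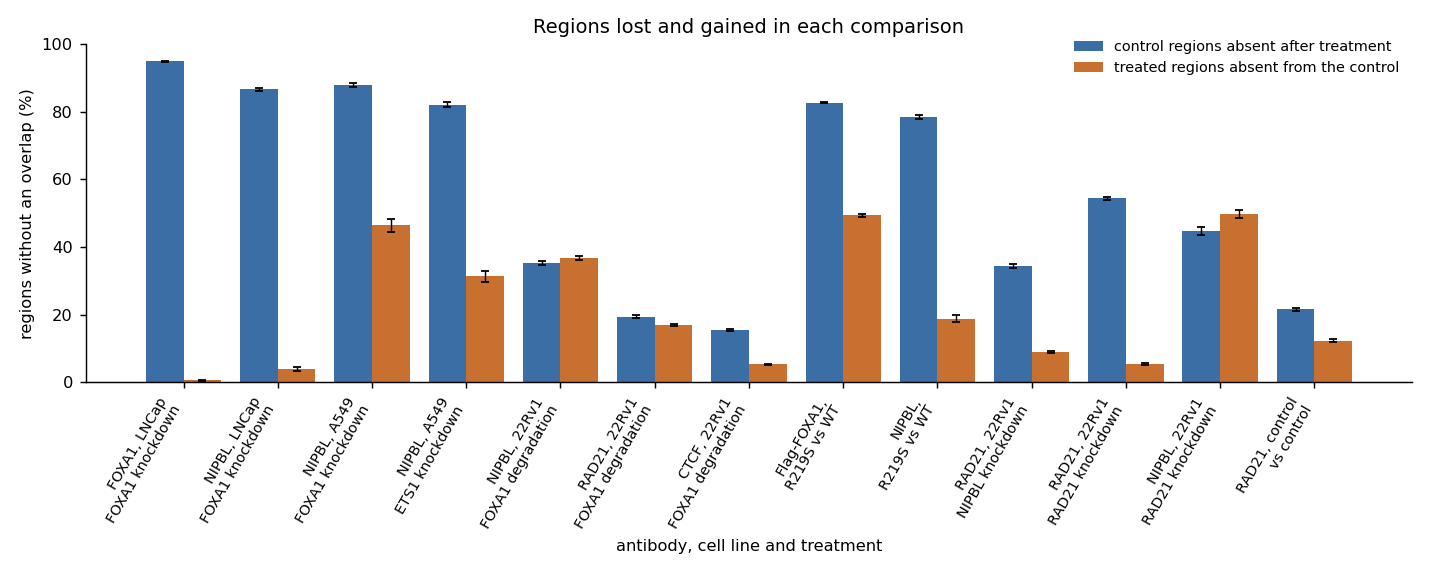
Share of control regions lost (blue) and of treated regions gained (orange), in percent, for each antibody, cell line and treatment; error bars are exact 95% binomial intervals. NIPBL lost 86.6% of its regions after FOXA1 knockdown in LNCap and 35.3% after FOXA1 degradation in 22Rv1, and the RAD21 control lists differed by 21.7% without any knockdown.

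Between 0 h and 24 h of FOXA1 degradation in 22Rv1, NIPBL calls differed more in place than in how much of the genome they covered. NIPBL had 26575 regions at 0 h and 26551 at 24 h; 35.3% were lost (34.7 to 35.8), 36.7% of the 24 h regions were new, and the covered genome rose by 10.3%. Loss depended on what else was bound. Of 11734 NIPBL regions at FOXA1 without CTCF, 54.9% were lost, beside 16.9% of 3964 at CTCF without FOXA1, 13.3% of 6534 at both and 32.0% of 4343 at neither. Sets of NIPBL regions matched on fold enrichment to those at FOXA1 without CTCF lost at most 37.5%. Among the strongest 10% of NIPBL regions the contrast was wider, with 61.6% lost at FOXA1 without CTCF and 1.90% (2 of 105) at CTCF without FOXA1, a difference of 59.7 points. The new NIPBL regions were poor in FOXA1: 27.5% overlapped Flag-FOXA1 and 36.6% CTCF, while 24 h regions present before overlapped them in 65.4% and 53.4%.

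**Figure D2:**
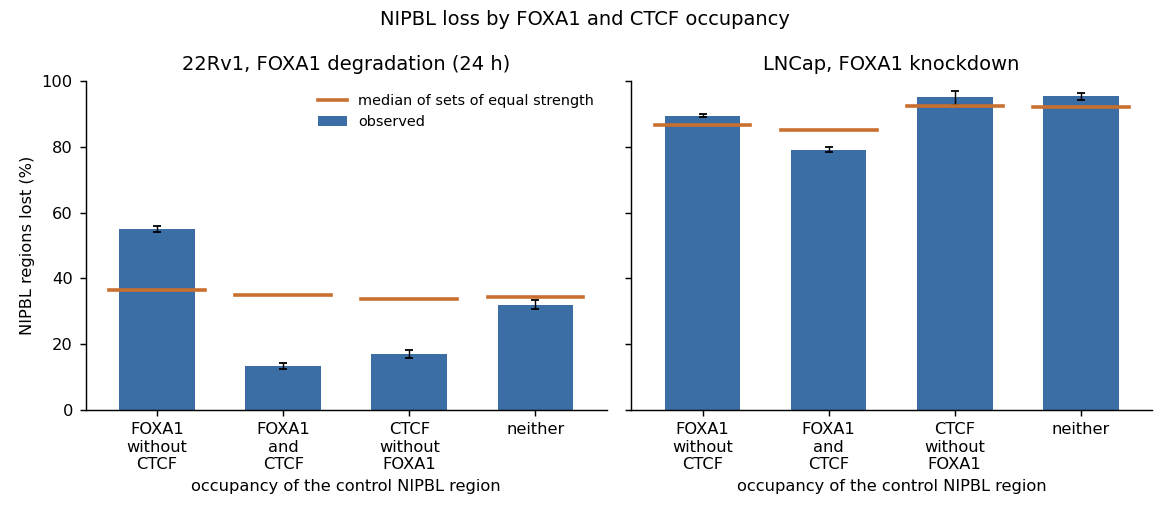
Share of control NIPBL regions lost, in percent, by the FOXA1 and CTCF occupancy of the region, after FOXA1 degradation in 22Rv1 and FOXA1 knockdown in LNCap; bars are observed shares with exact 95% binomial intervals and orange lines are medians of 10000 random sets matched on fold enrichment. In 22Rv1 the class with FOXA1 and no CTCF lost 54.9%, above its matched sets, and in LNCap the classes lay between 79.2% and 95.3%.

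Taken over all strengths, each of the 4 classes was missing from a list made without degradation more often than it was lost, and the contrast between FOXA1 without CTCF and CTCF without FOXA1 was smaller there. Of the 0 h NIPBL regions 52.5% were found in the replicate 1 list of 22Rv1 cells with wild-type FOXA1, beside 64.7% at 24 h. Lists of equal length were not compared here. The wild-type list was shorter, with 18533 regions against 26551 at 24 h, which by itself makes it miss more regions. Regions at FOXA1 without CTCF were missing from that list in 57.5% of cases, those at CTCF without FOXA1 in 40.4%. Among the strongest 10%, contrasted after the data were seen, these were 43.3% and 11.4%, a difference of 31.8 points, with fewer regions at FOXA1 without CTCF missing there than lost at 24 h. In a comparison chosen after seeing the data, 0 h regions also present in that wild-type list lost 13.7%: 29.8% at FOXA1 without CTCF and 4.49% at CTCF without FOXA1. The source of the FOXA1 list mattered as well. With LNCap FOXA1 regions the difference between these classes was 14.6 points instead of 38.0. The wider difference between all FOXA1 regions and all others, not among the comparisons fixed beforehand, changed from 15.2 points to -12.7 points. NIPBL regions found at FOXA1 in the LNCap list alone lost 16.0%, those in the Flag-FOXA1 list alone 51.3%, those in both 38.5% and those in neither 41.0%. H3K27ac separated the regions further, since marked NIPBL regions lost 17.4% and unmarked ones 70.2%. A similar contrast was present without degradation, in a check chosen after seeing the data. Of the unmarked regions 79.1% were missing from the wild-type replicate 1 list. Of the marked regions 28.9% were missing where H3K27ac was kept at 24 h and 62.9% where it was lost. The separation by H3K27ac cannot therefore be ascribed to degradation. Among marked regions 31.9% were lost at FOXA1 without CTCF and 6.24% at CTCF without FOXA1; among unmarked regions these shares were 85.6% and 40.7%.

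The 5 strongest NIPBL regions lost in 22Rv1 all overlapped Flag-FOXA1, and 1 of them overlapped CTCF. They lay on chromosome 5 (158615919 to 158616847, fold enrichment 58.0), chromosome 4 (34923707 to 34924802, 53.0), chromosome 2 (180438724 to 180439569, 50.3; 144975207 to 144976211, 48.5) and chromosome 17 (50496298 to 50497221, 50.0). The 5 strongest kept all overlapped Flag-FOXA1 too, and 4 of them overlapped CTCF, including regions on chromosome 3 (177075714 to 177078486, 69.5) and chromosome 9 (117670162 to 117671029, 47.2). A region on chromosome 17 (45972558 to 45974228, 47.1) was among the 5 strongest kept NIPBL regions here, and overlapping calls were among the 5 strongest kept after FOXA1 knockdown in LNCap, after both knockdowns in A549 and after RAD21 knockdown in 22Rv1.

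RAD21 changed less than NIPBL after FOXA1 degradation, and its strong regions stayed. RAD21 went from 41263 to 39805 regions, with 19.5% lost (19.1 to 19.9) and 16.9% of the 24 h regions new. That loss lay between the differences of the control RAD21 lists of the knockdown experiments, where 21.7% of the regions of one were absent from the other and 12.4% in the opposite direction. The weakest of 4 strength groups of RAD21 regions lost 46.7% and the strongest lost 0.0774% (8 of 10341). RAD21 regions without CTCF lost 55.5% and those with CTCF 12.4%, a difference of 43.1 points. Between the control RAD21 lists, made without degradation, this difference was 38.4 and 55.9 points, so it cannot be ascribed to degradation. Among regions without CTCF, 59.9% were lost at FOXA1 and 44.9% away from it. The strongest lost RAD21 regions lay on chromosome 18 (69971977 to 69973193, fold enrichment 28.3) and chromosome 12 (73922537 to 73923950, 27.9), and both carried FOXA1 and H3K27ac, the first also CTCF. The strongest kept region, on chromosome X (10087298 to 10088150, 130.1), carried CTCF without FOXA1.

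RAD21 was lost most often where the NIPBL region at the same place was lost, although most lost RAD21 regions lay elsewhere. Of 8038 lost RAD21 regions 2044 lay at lost NIPBL, 1540 at kept NIPBL and 4454 at no NIPBL. Where RAD21 lacked CTCF and the NIPBL region underneath was lost, 94.7% of 1932 RAD21 regions were lost, while matched sets of equal strength lost 33.5% to 42.1%. Where NIPBL was kept 29.2% of 3273 were lost, and where there was no NIPBL 62.1% of 1560. At CTCF these shares were 18.1%, 8.91% and 13.0%. In a check chosen after seeing the data, the same RAD21 regions without CTCF were looked up in the RAD21 control lists of the knockdown experiments, made without degradation. Of those at lost NIPBL 95.5% and 91.3% were missing there, and of those at kept NIPBL 77.3% and 75.9%. Most regions of both classes were therefore not called in the other experiments, which leaves little room for a difference there. NIPBL also followed H3K27ac, losing 85.5% of 1185 regions where H3K27ac was lost and 12.6% of 16264 where it was kept. In the wild-type replicate 1 list, without degradation, 62.9% and 28.9% of these NIPBL regions were missing.

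**Figure D3:**
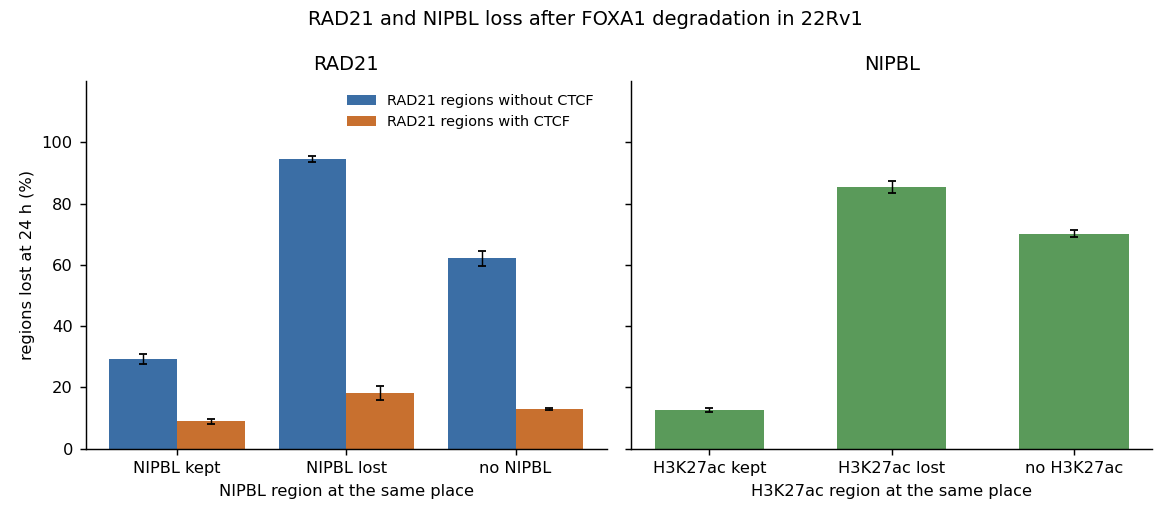
Left, share of 0 h RAD21 regions lost at 24 h in percent, with and without CTCF, by the fate of the NIPBL region at the same place; right, share of 0 h NIPBL regions lost by the fate of H3K27ac. Error bars are exact 95% binomial intervals, and RAD21 without CTCF at lost NIPBL reached 94.7%.

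CTCF and H3K27ac changed moderately after FOXA1 degradation. CTCF went from 59253 to 53260 regions, with 15.5% lost (15.2 to 15.8) and 5.38% of the 24 h regions new; with lists of equal length 9.63% were lost. None of the 14841 CTCF regions in the strongest of 4 groups was lost (0%, upper limit 0.0249%), and 52.3% of the weakest group were. CTCF regions with FOXA1 lost 12.5% and those without 16.4%. The strongest kept CTCF region lay on chromosome 16 (60252 to 61625, fold enrichment 139.4) and the strongest lost one on chromosome 20 (38726559 to 38727011, 18.3). For H3K27ac, 16.2% ± 0.366 (SD, n = 2) of the 0 h regions were absent from both 24 h lists and 27.3% ± 1.06 (SD, n = 2) of the 24 h regions were absent from both 0 h lists. List against list, paired by replicate number, 20.5% ± 0.345 (SD, n = 2) of the 0 h regions were absent at 24 h, and 20.5% ± 1.08 (SD, n = 2) with lists of unlike number. That was above the 16.2% ± 0.0388 (SD, n = 2) that 0 h replicates missed of each other. It was within 1 SD of the mean for 24 h replicates, 18.7% ± 2.24 (SD, n = 2), though slightly above both of their values, 17.1% and 20.3%. In the opposite direction, paired by replicate number, 32.7% ± 1.19 (SD, n = 2) of the 24 h regions were absent at 0 h, above both. Limited to the widest 1 in 3 regions of each list, the loss was 8.56%.

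H3K27ac regions called in both replicates changed more between times than between other pairings of the lists. Of 29139 such regions at 0 h, 2889 (9.91%) were absent from both 24 h lists, and 4775 of 31506 at 24 h (15.2%) were absent from both 0 h lists. The other 2 ways to pair the 4 lists gave 417 to 561 such regions (1.56% to 2.09%), and with 3 pairings no test can pass 0.05. Lost H3K27ac regions overlapped FOXA1 in 69.4% of cases, CTCF in 11.7% and lost NIPBL in 38.7%; kept ones overlapped them in 59.6%, 43.7% and 7.75%. Gained H3K27ac regions seldom held FOXA1 (14.1%). Of the gained regions 15.6% (744) held a 24 h NIPBL region and 11.7% (558) a gained one. Of the H3K27ac regions present before, 64.0% (17105) held a 24 h NIPBL region and 15.7% (4192) a gained one. Gained NIPBL was thus not more frequent at gained H3K27ac, but it made up more of the NIPBL found there.

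After knockdown of NIPBL or of RAD21 in 22Rv1 fewer RAD21 regions were called, and weak regions were lost most. NIPBL knockdown took RAD21 from 33226 to 23989 regions, with 34.4% lost (33.8 to 34.9) and 9.05% of the treated regions new. RAD21 knockdown took it from 29669 to 14384, with 54.4% lost (53.8 to 54.9) and 5.42% new. The strongest of 4 groups lost 2.75% and 12.1%, and the weakest 64.9% and 87.2%. Set against each other, the RAD21 control lists of these experiments differed by 21.7% of regions in one direction and 12.4% in the other. Among control regions found in both control lists, a restriction chosen after seeing the data, 22.7% and 48.6% were lost. With lists of equal length the losses were 19.8% and 24.2%. Of the 5894 regions in both controls that were lost after NIPBL knockdown, 85.4% were also lost after RAD21 knockdown, against at most 69.8% in sets of equal strength. More regions, 12614, were lost after RAD21 knockdown, and 5031 were lost after both.

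**Figure D4:**
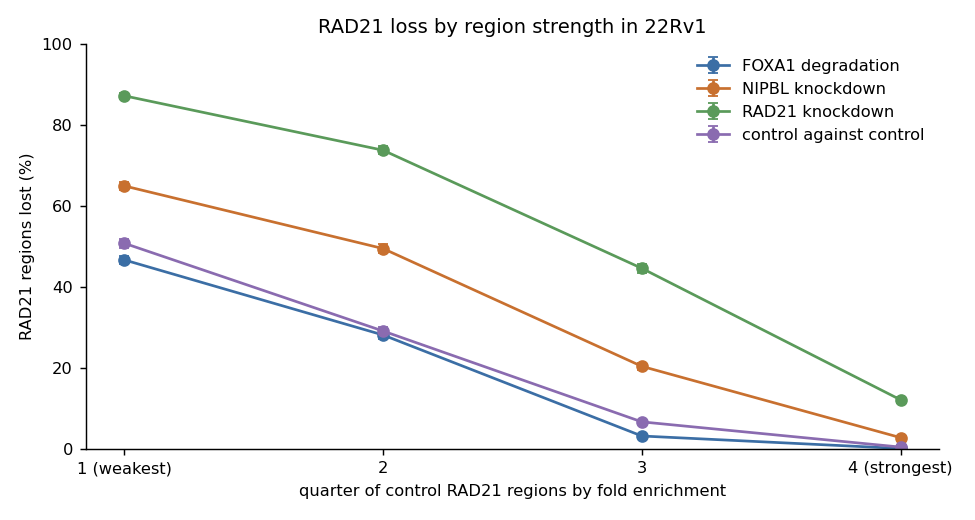
Share of control RAD21 regions lost, in percent, by strength group (1 to 4, fold enrichment) in 22Rv1 after FOXA1 degradation, NIPBL knockdown and RAD21 knockdown, and between the control lists of the knockdowns; error bars are exact 95% binomial intervals. In the strongest group the shares were 0.0774%, 2.75%, 12.1% and 0.421%.

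RAD21 regions without CTCF were lost more often in both knockdowns, but also between controls. The difference from regions with CTCF was 33.2 points after NIPBL knockdown and 37.6 points after RAD21 knockdown, and it was 38.4 and 55.9 points between the control lists. RAD21 regions at NIPBL lost 31.5% after NIPBL knockdown and those away from NIPBL 35.2%; after RAD21 knockdown these were 56.1% and 53.8%. NIPBL itself did not shrink when RAD21 was knocked down. It went from 6522 to 7228 regions, 44.7% were lost (43.5 to 45.9), 49.9% of the treated regions were new, and the covered genome rose by 9.47%. Both lists were short beside the NIPBL list at 0 h, which held 91.5% of the control regions and 89.85% of the treated ones. Most of the new regions were therefore called there without RAD21 knockdown. Under RAD21 knockdown, NIPBL regions at FOXA1 lost 40.0% and those elsewhere 56.5%. A NIPBL list under NIPBL knockdown was not analysed here, so that knockdown was not checked. The strongest RAD21 region lost after NIPBL knockdown lay on chromosome 18 (78015629 to 78016108, fold enrichment 34.7) and after RAD21 knockdown on chromosome 19 (33467074 to 33467596, 23.7). The strongest kept lay on chromosome 1 (225662416 to 225663256, 60.5) and chromosome 3 (48506797 to 48508642, 50.4).

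The FOXA1 mutant R219S bound a smaller and different set of regions, and NIPBL in its presence had fewer regions. Flag-FOXA1 went from 100536 regions for wild type to 33625 for R219S; 82.7% of the wild-type regions were absent (82.4 to 82.9) and 49.4% of the R219S regions were absent from wild type. Regions kept by R219S were more often marked as active chromatin. H3K27ac marked 74.3% of the shared regions, 49.4% of those bound by R219S alone and 8.38% of those bound by wild type alone. CTCF followed the same order, at 41.1%, 36.8% and 9.13%. The strongest wild-type region lost lay on chromosome 2 (213804640 to 213805868, fold enrichment 75.6), as did the strongest kept one (237733255 to 237734218, 77.8).

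Among the classes compared, NIPBL in R219S cells was reduced least where wild-type FOXA1 and R219S were both bound. In the lists pooled over both replicates NIPBL went from 19301 to 5154 regions, with 78.4% lost (77.8 to 79.0), 18.8% of the R219S regions new and a covered genome that fell by 73.1%. In replicate 1 alone it went from 18533 to 1349 regions, with 93.1% lost. NIPBL regions at Flag-FOXA1 bound by wild type alone lost 97.4%, those at Flag-FOXA1 shared by both proteins 61.7%, and those with no Flag-FOXA1 99.0%. Sets of equal strength matched to the shared class lost 76.1% to 78.9%. NIPBL regions at Flag-FOXA1 of R219S alone were not made a class, so they are not in this ranking. Limited to pooled regions also in the replicate 1 list, the classes lost 97.0%, 60.9% and 91.0%, the last with 510 regions instead of 5224. In replicate 1, split in this way after the data were seen, the shared class again lost least but the gap was much smaller, at 99.5%, 89.9% and 99.5%. Its loss at all wild-type Flag-FOXA1 regions was 92.2% and away from them 94.97%. Of the pooled wild-type NIPBL regions 5749 were absent from replicate 1; 98.0% of these were lost, and 11.7% carried H3K27ac. The other 13552 lost 70.1%, a restriction chosen after seeing the data, and 83.2% of them carried H3K27ac. Whether the pooled lists were made from the labelled libraries could not be checked, and the 78.4% rests on them. The 5 strongest lost regions of the pooled list, such as that on chromosome 2 (38708859 to 38710040, fold enrichment 68.9), overlapped none of FOXA1, CTCF, H3K27ac and RAD21. The strongest kept one lay on chromosome 1 (911363 to 913194, 47.5).

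In mouse, libraries of the same tissue were more alike than those of different tissues for both NIPBL and FOXA1. Libraries of the same tissue shared a mean Jaccard index, the overlap in base pairs divided by the union, of 48.2% for NIPBL and 51.0% for FOXA1; libraries of different tissues shared 25.8% and 17.2%. The gap of 22.4 points for NIPBL was larger than under any of the other ways to pair the 6 libraries, which reached at most 10.2 points, and the gap of 33.8 points for FOXA1 exceeded 11.2 points. A one-sided exact permutation test over the 15 pairings gave p = 0.0667 for each antibody, the smallest p this design allows. Liver held 17915 NIPBL regions called in both of its libraries and in no library of the other tissues, lung 3685 and stomach 1094; these were 51.8%, 20.9% and 8.84% of the NIPBL regions called in both libraries of the tissue. The NIPBL lists differed in length, with 40925 and 54533 regions in liver, 24589 and 28118 in lung, and 23226 and 15783 in stomach. Tissue-only shares depend on these lengths, and lists of equal length were not compared for them. The strongest tissue-only regions lay on chromosome 17 in liver (43269961 to 43270838, fold enrichment 67.5), chromosome 11 in lung (90425317 to 90426114, 26.3) and chromosome 9 in stomach (31437826 to 31438207, 13.5). All 15 of the strongest, 5 per tissue, overlapped FOXA1 of the same tissue.

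NIPBL lay at the tissue's own FOXA1 regions often in liver and stomach and less often in lung. The share was 80.6% ± 2.70 (SD, n = 2) in liver, 68.6% ± 6.68 (SD, n = 2) in stomach and 33.8% ± 4.80 (SD, n = 2) in lung, against 3.10%, 1.47% and 1.87% for shifted regions. Liver NIPBL overlapped FOXA1 of lung in 19.5% and of stomach in 29.0%. The liver FOXA1 set was the longest, with 59770 regions. Limited to 33858 FOXA1 regions per tissue, a setting added after the data were seen, the own-tissue share was 63.0% in liver, 68.6% in stomach and 33.1% in lung, so liver no longer ranked above stomach. With the full sets lung NIPBL overlapped liver FOXA1 in 47.0% ± 2.35 (SD, n = 2) and stomach FOXA1 in 39.9% ± 2.97 (SD, n = 2), both above its own tissue; with 33858 regions per tissue it overlapped stomach FOXA1 most (39.9%), and liver FOXA1 in 33.9%. Among NIPBL regions of 1 tissue alone the own-tissue share was 96.2% in liver, 87.3% in stomach and 40.1% in lung, and the lung-only regions overlapped liver FOXA1 in 5.46%. The lung value depended on the FOXA1 list. Replicate 2 of NIPBL against replicate 2 of FOXA1 (61486 regions) gave 51.9%, and replicate 1 against replicate 1 (41216 regions) gave 37.5%. Against the lung FOXA1 regions called in both, the order was reversed, with 37.2% for NIPBL replicate 1 and 30.4% for replicate 2. Paired by replicate, liver (91.4% against 82.95%) and stomach (81.7% against 73.7%) were also higher in replicate 2.

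**Figure D5:**
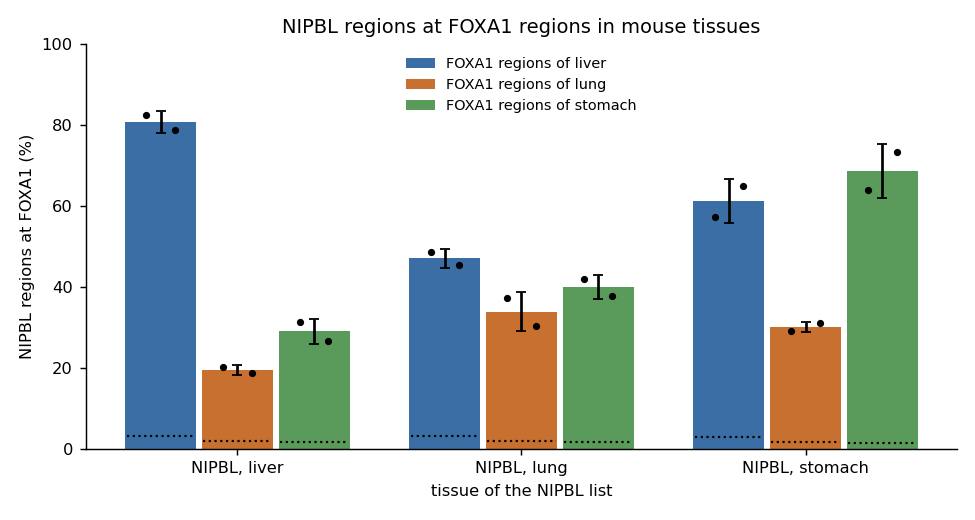
Share of mouse NIPBL regions, in percent, that overlapped FOXA1 regions called in both replicates of liver, lung or stomach; bars are means of 2 libraries, points the libraries, error bars SD and dotted lines shifted regions. Liver and stomach NIPBL overlapped FOXA1 of the same tissue most, and lung NIPBL overlapped liver FOXA1 most (47.0%) with these sets of unequal length, but stomach FOXA1 most (39.9%) with equal ones.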

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

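The 2 tests of the LNCap pattern and how they were read, the test of the share lost in 22Rv1, and the search for class differences in the strongest 10% of regions and in further lists made without degradation were chosen after the result was seen; the other tests of the 22Rv1 pattern were written before, when overall class shares were already known.

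The genome covered by NIPBL regions, and the difference in loss between classes, changed with opposite sign in different cell lines. The genome covered by NIPBL regions changed by +10.3% after FOXA1 degradation in 22Rv1, by -90.0% after FOXA1 knockdown in LNCap and by -78.3% after FOXA1 knockdown in A549. The difference in NIPBL loss between regions at FOXA1 without CTCF and regions at CTCF without FOXA1 was 38.0 points in 22Rv1 and -5.56 points in LNCap. These differences between lines were not tested, since each rests on 1 list per condition. The rise in 22Rv1 is small beside the spread of NIPBL lists made there without degradation, mutant or knockdown, which covered 3.06 to 16.95 Mb, so a rise caused by FOXA1 loss is not shown. The class difference used Flag-FOXA1 regions in 22Rv1 and LNCap FOXA1 regions in LNCap; with LNCap FOXA1 regions in both it was 14.6 points in 22Rv1, and the difference between all FOXA1 regions and all others was negative in both lines (-12.7 and -9.34 points). Cell line and method of removal changed together, and the lists of the degradation were called at a stricter q.

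In 22Rv1, 54.9% of NIPBL regions at FOXA1 without CTCF were lost after degradation. Region strength is argued against as the whole cause, because sets matched on fold enrichment, -log10 q or width lost at most 38.1%. Over all strengths, a wild-type list made without degradation argues against poor repeatability of NIPBL calls as the whole cause of the difference from CTCF without FOXA1. There the difference was 17.0 points against 38.0, or 44.8% of it (40.4 to 49.1, counting error only, limit 50%), so the margin was narrow. The strongest 10% of regions, at 53.3% (41.8 to 64.6), did not decide. In the pooled wild-type, RAD21 knockdown control and LNCap control lists the difference was 7.98, -2.33 and 3.72 points. These lists cannot decide. The RAD21 knockdown control list missed 81.2% and 83.6% of these classes, which leaves little room for a difference. The origin of the pooled list was not checked, and LNCap is another line. For the share lost itself, poor repeatability and an effect of degradation cannot be told apart, because 57.5% of the regions were missing from the wild-type list over all strengths, more than were lost, but in the strongest 10% fewer were missing (43.3%) than lost (61.6%). The wild-type list was also shorter than the 24 h list, with 18533 against 26551 regions, which by itself makes it miss more regions. A difference in depth between the 0 h and 24 h libraries stays open and untested.

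In LNCap, 85.9% of NIPBL regions at FOXA1 were lost. A lower yield of the knockdown library, acting alike on regions of equal strength, cannot be told apart from a widespread loss of NIPBL: the share lay at percentile 17.4 of sets matched on -log10 q, but below all sets matched on fold enrichment. A loss preferring FOXA1 regions stays open too: the share lay no higher than percentile 37.3 under any of the 3 matching measures, but FOXA1 held 92.7% of NIPBL regions, so few served as the contrast. At FOXA1 without CTCF the loss of 89.5% lay above all sets matched on fold enrichment and on -log10 q, and at percentile 60.9 of those matched on width, while NIPBL was lost more where the FOXA1 region was kept (87.9%) than where it was lost (85.7%). An effect of FOXA1 knockdown on NIPBL that does not depend on FOXA1 at the region remains open and untested.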

How the results depend on the processing

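Alternatives that require presence in a second control list, FOXA1 sets of equal length in mouse, and those for NIPBL loss at FOXA1 against all other regions in 22Rv1, were chosen after seeing the data. Over 24 results and 88 alternatives, 31 values stayed within the interval or replicate spread of the reported value, 56 moved beyond it and 1 changed sign. The permutation results stayed in direction at p = 0.0667, with gaps of 18.4 to 23.3 points for NIPBL and 36.2 to 39.1 points for FOXA1. Where no reason is given, the cause was not tested.

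The sign change was NIPBL loss at FOXA1 minus other regions in 22Rv1: 15.2 points with Flag-FOXA1, -12.7 points with LNCap FOXA1 regions. The same list took the NIPBL class difference in 22Rv1 from 38.0 to 14.6 points.

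With an overlap of at least 50% of the shorter region, losses in the degradation became 36.2% for NIPBL, 20.5% for RAD21 and 17.5% for H3K27ac. Flag-FOXA1 absent in R219S became 83.8%, NIPBL absent in R219S 79.2%, and NIPBL lost under RAD21 knockdown 48.7%. FOXA1 minus other regions became 17.4 points, and the RAD21 difference by CTCF 45.9 points after degradation and 35.4 points after NIPBL knockdown. By construction, shared regions can become lost under this rule, and not the reverse, for loss shares.

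With -log10 q of at least 5, NIPBL loss became 90.3% in LNCap, 87.3% in A549 under FOXA1 knockdown, 83.7% for R219S and 51.0% under RAD21 knockdown. CTCF loss became 14.3%, Flag-FOXA1 loss 85.3% and RAD21 loss under RAD21 knockdown 55.0%. The NIPBL class difference in 22Rv1 became 42.2 points, and NIPBL loss at FOXA1 minus other regions 21.9 points in 22Rv1 and -3.76 points in LNCap. The RAD21 difference by CTCF became 44.8 points after degradation, 30.4 points under NIPBL knockdown and 33.8 points under RAD21 knockdown. Stomach NIPBL at FOXA1 became 61.9%.

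With lists of equal length, loss became 49.3% for FOXA1 and 50.2% for NIPBL in LNCap, 75.2% under FOXA1 knockdown and 61.1% under ETS1 knockdown in A549, 18.1% for RAD21 and 9.63% for CTCF after degradation, 78.4% for Flag-FOXA1 and 71.3% for NIPBL in R219S. RAD21 loss became 19.8% under NIPBL knockdown and 24.2% under RAD21 knockdown, and NIPBL loss under RAD21 knockdown 48.2%. Shortening the longer list removes its weaker regions by construction.

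For H3K27ac, the widest 1 in 3 regions gave 8.56%, lists of equal length by width 18.4%, lists paired as a block by replicate number 20.5%, and lists without a replicate 20.3% to 20.8%; each of the last 2 settings uses fewer 24 h lists by construction. Paired as a block by replicate, mouse NIPBL at FOXA1 became 87.2% in liver, 44.7% in lung and 77.7% in stomach. Without a replicate the ranges were 82.9% to 91.4%, 37.5% to 51.9% and 73.7% to 81.7%; FOXA1 regions of 1 library replace those called in both. With FOXA1 sets of equal length liver became 63.0%, since fewer FOXA1 regions remain by construction.

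Limited to regions also in the wild-type replicate 1 list, NIPBL loss after degradation was 13.7%, the class difference 25.3 points, FOXA1 minus other regions 12.8 points and NIPBL loss in R219S 70.1%; lists of replicate 1 alone gave 93.1%. Limited to regions also in the other control list, RAD21 loss was 22.7% under NIPBL knockdown and 48.6% under RAD21 knockdown, with differences by CTCF of 24.6 and 30.0 points.

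Gene-list and motif analyses, with their alternatives, were not run for want of gene positions and sequence of the builds used. Depth is unknown for every list, so a shorter list cannot be separated here from a shallower library.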

Other observations

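The tests of the lung pattern were written before their results were seen, although the overlap per lung library was already known, and the judgement that lung-only regions leave the question open was made after their values were seen; the counts in the other paragraphs were made after the data were seen.

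Lung NIPBL regions overlapped lung FOXA1 less often than liver FOXA1, by -13.2 points (SD 2.45, n = 2). When the FOXA1 lists were limited to 33858 regions each, the mean gap was -0.86 points (SD 2.65, n = 2), with 1.01 points in replicate 1 and -2.73 points in replicate 2. With equal lengths most of the gap was gone, but list length as the whole cause and a remaining difference between tissues cannot be told apart, because the libraries differed in sign. Among NIPBL regions of lung alone the overlap with lung FOXA1 exceeded that with liver FOXA1 by 34.6 points, but choosing regions without liver NIPBL lowers the liver overlap by itself, so this does not decide whether shared regions explain the gap. The overlap with lung FOXA1 was 40.1% at lung-only NIPBL regions and 33.9% at the 8237 regions called in all 6 libraries.

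The pooled wild-type NIPBL list held 491 regions with fold enrichment of at least 20 that were absent from the list of replicate 1. All 491 were absent from the R219S list, and 8 were present in the NIPBL list at 0 h. Of the 1349 R219S regions of replicate 1, 90.9% were in the pooled R219S list, and 92.3% of the 5154 pooled regions were in the NIPBL list at 0 h.

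Of the 24 h RAD21 regions that were new after FOXA1 degradation, 63.9% overlapped a 24 h NIPBL region, new or present before, against 33.7% of the RAD21 regions present before. The new regions also held CTCF less often, in 38.5% against 91.2%. At 0 h, 1560 of 6765 RAD21 regions without CTCF and 26753 of 34498 with CTCF lay at no NIPBL. The contrast was not split by CTCF, so being new and lacking CTCF cannot be told apart here. The NIPBL control list of the RAD21 knockdown was short, and 91.5% of its 6522 regions were found in the NIPBL list at 0 h.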
